A study of Homo sapiens with 6 samples.

How the data were processed

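PC3 cells, an established human prostate cancer line, were grown as subcutaneous tumours in NOD/SCID mice, which lack functional T and B cells. Per the labels' protocols, treatment started at a tumour volume of about 100 mm3 and lasted 14 days, with daily intraperitoneal injections of either 20 nmol per mouse of [D-Lys3]-GHRP-6, a peptide antagonist of the ghrelin receptor, or phosphate-buffered saline (PBS). The labels assign 3 xenografts to each of the 2 groups, so there were 6 libraries. Polyadenylated RNA was sequenced from libraries made with a stranded kit. The labels name 2 alternative sequencing kits without saying which library was run with which, so a kit batch was not assigned to any library.

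The authors deposited 1 table per library with 27033 rows, each a gene at a locus, holding the FPKM (fragments per kilobase of transcript per 1000000 mapped fragments), its confidence bounds and a quantification status, per the file headers. Per the submitters' processing notes, the tools were TopHat2 2.0.9, Bowtie2 2.1.0 and Cufflinks 2.1.1, with the builds hg19 and GRCh37. The annotation, the normalization options, the use of strand in quantification and the treatment of multiply mapped reads are not given in the sources used here. Loci on hg19 haplotype chromosomes are among the rows, so genes of the major histocompatibility complex are split over several rows. FPKM values already divide by transcript length and depth. They therefore depend on the authors' length model, and a few very abundant transcripts can lower the values of all others in a library.

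The deposited FPKM tables hold no read counts. The ratio of each value to its confidence bound implied between 22.2 and 27.7 fragments times 1000000 per library. Of the low rows with 1 transcription start site and between 4 and 15 implied fragments, 48.1% to 50.5% came within 0.02 of a whole number, so counts were not recovered and no count test was run. Counting intervals are not given for the same reason. The precision of every value below is the spread between the 3 xenografts of a group.

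Rows with the same gene symbol were summed (602 symbols had more than 1 row, and 1 row had no gene name), and 24 rows with a status other than OK in any library were left out. The test matrix was log2(FPKM + 1), with a pseudocount of 1, for the 12630 genes with a mean FPKM of at least 1 over the 6 libraries. A fold change is on this scale, which understates the change of genes with low values. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (a linear model per gene with moderated variances and a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design and all alternatives except 3 were fixed before the data were examined.

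Of 38 gene lists written before the data were examined, the 29 with at least 5 measured members were tested with camera (limma), which compares a list with all other measured genes, using a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 29 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were the alternatives. Markers of mouse host cells were summarised per library as the mean log2(FPKM + 1) over each marker list and compared with an exact two-sided permutation test, which cannot give a p below 0.1 with 3 against 3 libraries.

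The rule for named genes took the 12 genes per direction with the largest fold change among those past the threshold, filled up with the smallest unadjusted p where fewer passed. Loci named only by number and small RNA genes were passed over. It also took the members of the ghrelin axis list and of the list of other reported targets of the peptide, and the members with the smallest p of each list described. Some planned results are not reported here.

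The alternatives were other pseudocounts (0.1 and 0.01), other filters (none, a mean FPKM of at least 5, an FPKM of at least 1 in 3 libraries), rescaling to TPM, median-of-ratios, upper-quartile and quantile normalization, the replicate number as a block, library weights, robust or untrended variance moderation, rows kept separate, status ignored, host marker genes left out, a host score covariate, and each library left out in turn. After seeing the data, 3 alternatives were added: a per-library trend with transcript length removed (loess, span 0.4), the same for GC content, and small RNA genes left out. Transcript length and GC content came from the GENCODE transcripts of GRCh38, matched by current and older symbols to 97.75% of the tested genes. No coordinates were taken from that annotation; those given below are hg19 as deposited.

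The test was checked on simulated data for the same comparison and 12630 genes, with the real means and moderated variances. Of 100 genes changed by 1 on the log2 scale 75% were recovered, and of 100 changed by 2 98% were recovered, with 7 false calls. With no gene changed, 0 genes and 0 lists were called. The simulated genes varied independently of each other, which the real genes of a list did not. The moderated variances were also taken as the true ones, so the shares recovered may be higher than in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.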

Results

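Gene expression was measured by RNA sequencing in 6 PC3 xenografts, 3 from mice given PBS and 3 from mice given [D-Lys3]-GHRP-6, which blocks the receptor for ghrelin, for 14 days (the treated group). The design text gives 3 mice per group. Summed FPKM per library ranged from 440918 to 589141, with the highest sum in treated replicate 2. MSMP, at 20392 to 28704 FPKM in the PBS libraries and 28420 in treated replicate 3, was not quantified in treated replicates 1 and 2. The sums are therefore not directly comparable, and with MSMP set aside every treated sum lay above every PBS sum. Between 12132 and 12716 genes reached an FPKM of at least 1.

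Treated replicate 2 stood apart from the other libraries. It lay at 51.97 on the first principal component, which held 43.7% of the variance, while the other libraries lay between -20.45 and -0.63. Its mean correlation with the other libraries was 0.9485, the lowest of the 6, and those of the others were 0.9625 to 0.9714. Its expression also fell off with transcript length. The median deviation from the gene mean on the log2 scale was 0.04 for transcripts around 576 nt and -0.17 for transcripts around 5677 nt. The trend with length was not confined to that library. The rank correlation of the deviations with length was 0.23, 0.16 and 0.20 in PBS replicates 1, 2 and 3. In treated replicates 1, 2 and 3 it was 0.09, -0.24 and -0.09, so the groups did not overlap. No 2 libraries had the same FPKM value for more than 1 tested gene, so none was a copy of another.

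**Figure D1:**
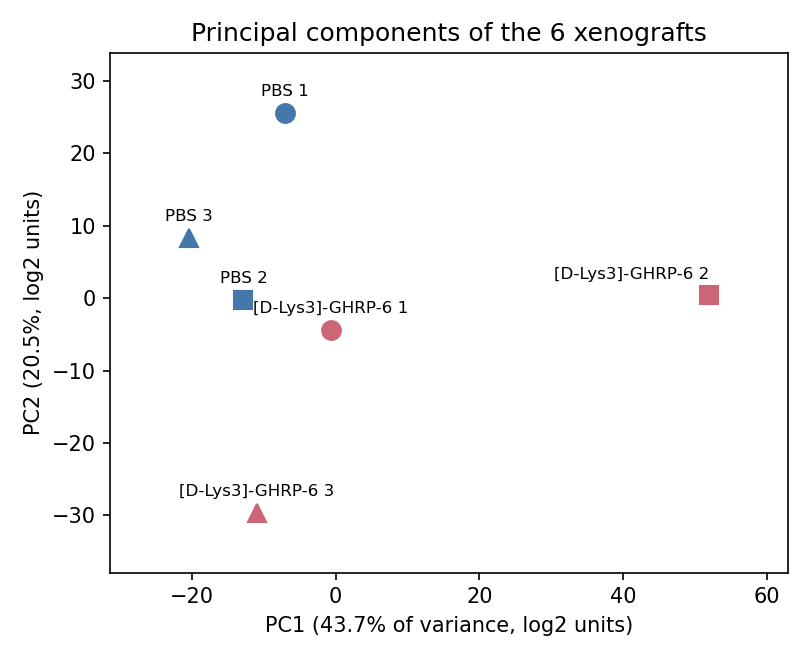
Scores of the 6 xenografts on the first and second principal components of log2(FPKM + 1) over the tested genes, in log2 units, with PBS in blue and [D-Lys3]-GHRP-6 in red and the shape giving the replicate. Treated replicate 2 lies at 51.97 on the first component, and the other libraries lie at or below -0.63.

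**Figure D2:**
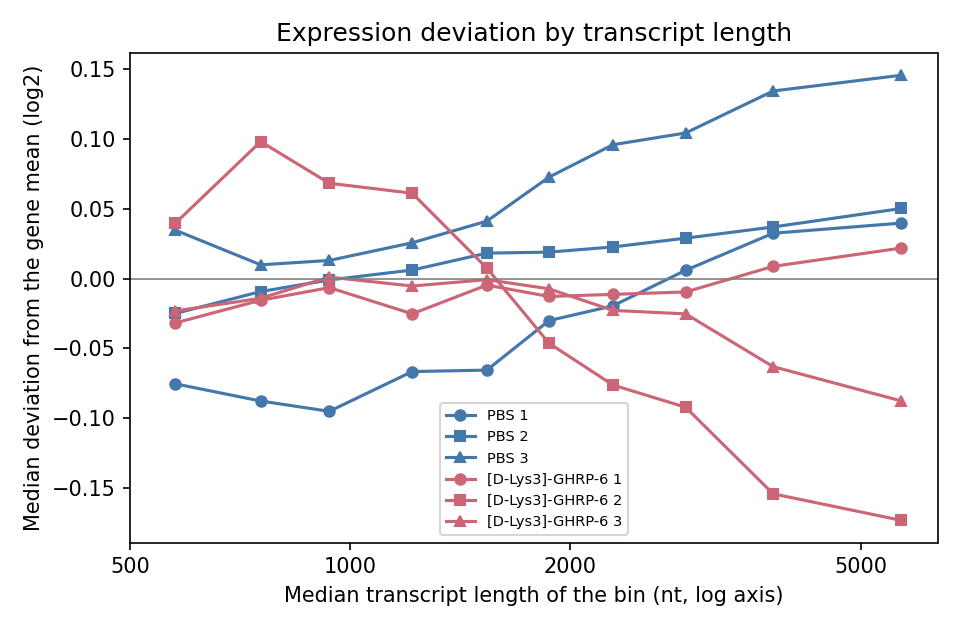
Median deviation of log2(FPKM + 1) from the gene mean, per library, in 10 bins of transcript length on a log axis. The line of treated replicate 2 goes from 0.040 in the bin of the shortest transcripts to -0.173 in the bin of the longest.

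The first question was whether the receptor and its ligand system were expressed in the tumours. GHSR, the ghrelin receptor and the intended target of the peptide, had 0 to 0.056 FPKM in the 6 libraries, far below the level of 1 FPKM used for testing. GHRL, which encodes ghrelin, had 0.61 ± 0.24 FPKM in PBS and 0.63 ± 0.46 in treated tumours (SD, n = 3 each). MBOAT4, the acyltransferase that activates ghrelin, stayed at or below 0.156 FPKM, and LEAP2, an endogenous antagonist of the receptor, at or below 0.893. PCSK1, GH1, IGF1, MLNR and CD36 were each below 0.2 FPKM, and GHRH and GHRHR were listed at 0 in all 6 libraries.

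Of the ghrelin axis list, 6 genes could be tested and none passed, over all genes or adjusted over the list alone. IGF2, a growth factor, was at 60.8 ± 43.3 FPKM in PBS and 136 ± 81.6 in treated tumours, with overlapping groups (log2 fold change 1.25, SE 0.56). GHR, the growth hormone receptor, was at 6.36 ± 1.85 and 8.24 ± 1.47 FPKM. IGF1R was at 1.63 ± 0.03 and 1.30 ± 0.21 FPKM. FURIN had log2 fold change 0.24 (SE 0.20), IGFBP3 -0.30 (SE 0.29) and GPR39, a relative of the ghrelin receptor, 0.06 (SE 0.15). The list as a whole did not pass (camera adjusted p = 0.446).

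Among other reported targets of the peptide, CXCR4, a chemokine receptor, was at 11.5 ± 6.53 FPKM in PBS and 4.80 ± 1.66 in treated tumours (log2 fold change -0.95, SE 0.45), and CCL5 was at 2.22 ± 0.19 and 1.75 ± 0.91 FPKM. Neither passed. The highest value in any library was 0.48 FPKM for HTR2C, 0.37 for HTR2A, 0.30 for HTR2B and 0.22 for CXCL12, while CCL3, CCL4, HTR1B and TACR1 were below 0.06 FPKM.

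The second question was which genes differed between treated and PBS tumours. No gene passed limma with adjustment over 12630 genes (smallest adjusted p = 0.131). At an unadjusted p under 0.05 there were 1053 genes, 411 higher and 642 lower in treated tumours, where 631.5 would be reached by chance. This count was 531 without PBS replicate 1, 333 without PBS replicate 3, 660 without treated replicate 2, 1709 without treated replicate 3 and 2027 with library weights, so it fell below the chance level without PBS replicate 1 or 3. The groups did not overlap for 2117 genes (16.76%, where chance gives 10% on average). Genes that vary together can carry both counts far from these averages in a single grouping. The other splits of the 6 libraries into 3 and 3 gave 102 to 1172 genes at an unadjusted p under 0.05. Genes without overlap were not counted in those splits, so neither count shows an excess over chance. The genes below are those with the smallest unadjusted p, and each has an adjusted p of 0.595.

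On the higher side, KLK4, a kallikrein protease gene of the prostate (chromosome 19, 51409608 to 51413994), was at 2.00 ± 0.19 FPKM in PBS and 6.98 ± 2.88 in treated tumours (log2 fold change 1.34, SE 0.27). It passed without treated replicate 2 (log2 fold change 1.66, adjusted p = 0.0415) and with library weights (adjusted p = 0.0103). KRT75, a keratin (chromosome 12, 52817854 to 52828110), was at 110 ± 71.3 and 327 ± 25.7 FPKM (log2 fold change 1.75, SE 0.39). APOBEC3G, a cytidine deaminase that restricts retroviruses, was at 70.9 ± 22.0 and 133 ± 20.6 FPKM. KCNK12, a potassium channel gene, was at 2.12 ± 0.55 and 5.41 ± 2.25 FPKM, and AK5, an adenylate kinase, at 2.41 ± 0.57 and 4.83 ± 0.76. CTSF, a lysosomal protease, had log2 fold change 0.69 and POLD4, a subunit of DNA polymerase delta, 0.50. MDP1, RAB4B and TRPT1 had log2 fold changes of 0.73, 0.52 and 0.51. EEF1E1-BLOC1S5 (1.47), a readthrough transcript, and DLG3-AS1 (0.80), an antisense transcript, share sequence or position with other genes, and the fragments assigned to them are uncertain.

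On the lower side, CXCL1 (chromosome 4, 74735109 to 74737019) and CXCL6, neutrophil-attracting chemokines, were at 55.2 ± 24.4 and 13.1 ± 1.17 FPKM in PBS and at 14.8 ± 6.84 and 4.76 ± 2.27 in treated tumours (log2 fold changes -1.83, SE 0.38, and -1.37, SE 0.28). CTGF, a matricellular growth factor, was at 48.7 ± 12.1 and 22.7 ± 4.55 FPKM (log2 fold change -1.06, SE 0.22). PTX3, a secreted pattern recognition protein, was at 58.0 ± 5.75 and 37.2 ± 3.46 FPKM, and ADAMTS1, a secreted metalloprotease, at 15.2 ± 3.77 and 7.57 ± 1.39. SERINC2 was at 17.8 ± 1.17 and 11.5 ± 0.44 FPKM, MISP at 14.6 ± 2.90 and 8.21 ± 0.28, and PHACTR3 at 9.98 ± 2.83 and 4.41 ± 1.28. YOD1, a deubiquitinase, had log2 fold change -0.91, the mucin gene MUC3A -1.13 and the keratin-associated KRTAP2-3 -0.87. COMMD3-BMI1, a readthrough transcript whose fragments are shared with its component genes, had log2 fold change -1.40 (SE 0.23).

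The third question was whether genes of a pathway moved together. Of 29 lists, 7 passed camera with the preset correlation, 2 higher and 5 lower in treated tumours. None passed with an estimated correlation (smallest adjusted p = 0.602) or with fry (smallest adjusted p = 0.199). With the preset correlation, the other 9 ways of splitting the 6 libraries into groups of 3 gave 4 to 11 lists, a range that includes the 7 of the real grouping. The ribosomal protein list passed in all 9 of them, oxidative phosphorylation in 8, the immediate-early list in 6, the cytokine list in 4, hypoxia and epithelial genes in 3 each and DNA replication in 0.

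**Figure D3:**
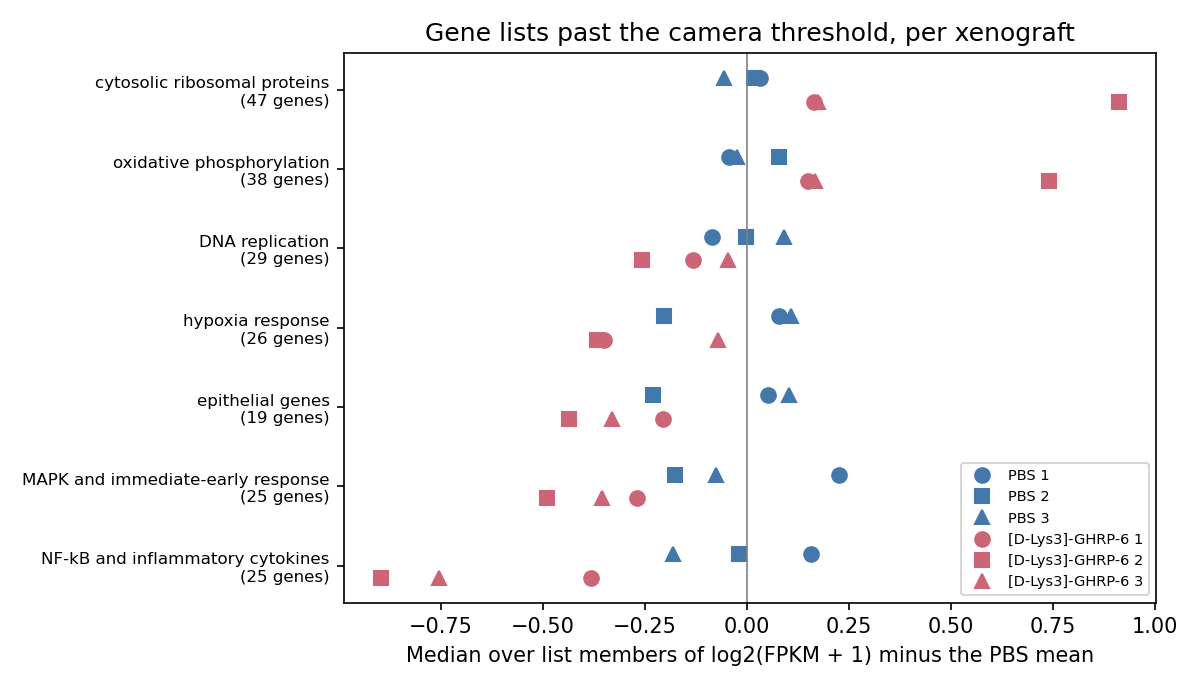
Median over the measured members of log2(FPKM + 1) minus the PBS mean, per xenograft, for the 7 lists that passed camera with the preset correlation (PBS blue, [D-Lys3]-GHRP-6 red, shape giving the replicate). Cytosolic ribosomal proteins lie at 0.166, 0.914 and 0.174 in treated replicates 1, 2 and 3, and the cytokine list at -0.382, -0.896 and -0.754.

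NF-kB targets and inflammatory cytokines were lower in treated tumours for 23 of 25 measured members, with a median log2 fold change of -0.61 (camera adjusted p = 6.8e-10; adjusted p = 0.602 with an estimated correlation). For 15 members all treated values lay below all PBS values, and 12 members passed adjusted over the list alone, 0 over all genes. CXCL8, a neutrophil chemokine, was at 26.2 ± 17.1 FPKM in PBS and 6.75 ± 0.85 in treated tumours. CSF2, a myeloid growth factor, was at 1.99 ± 0.45 and 0.75 ± 0.20 FPKM, and the cytokine IL6 at 3.25 ± 1.14 and 1.11 ± 0.44. The NF-kB inhibitors NFKBIA and TNFAIP3, themselves NF-kB targets, were at 66.3 ± 2.04 and 5.25 ± 1.32 FPKM in PBS and at 46.9 ± 7.82 and 2.63 ± 0.62 in treated tumours. LCN2 and SAA1 were the 2 members with higher means in treated tumours. PBS replicate 1 held the highest CXCL8 and CXCL1 values, 45.7 and 82.2 FPKM.

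**Figure D4:**
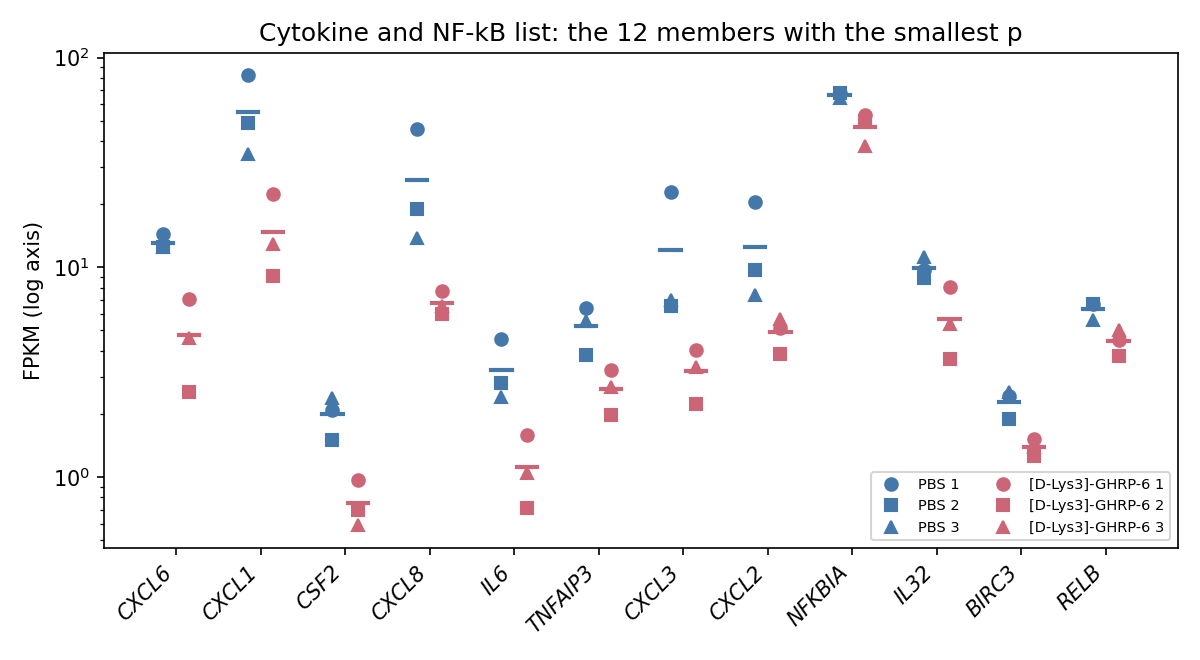
FPKM on a log axis for the 12 members of the cytokine list with the smallest p, per xenograft, with bars at the group means (PBS blue, [D-Lys3]-GHRP-6 red, n = 3 each). For CXCL8 the treated values lie between 6.01 and 7.68 FPKM and the PBS values between 13.8 and 45.7.

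MAPK and immediate-early genes were lower for 23 of 25 members (median log2 fold change -0.43, camera adjusted p = 1.4e-06; adjusted p = 0.602 with an estimated correlation). CTGF was the 1 member to pass adjusted over the list alone. MYC, a transcription factor of growth, was at 48.8 ± 4.75 FPKM in PBS and 33.5 ± 4.91 in treated tumours, and JUNB at 33.8 ± 3.59 and 23.2 ± 4.24. IER3 was at 161 ± 19.6 and 116 ± 6.98 FPKM. Without PBS replicate 1, which held the highest FOS (5.67 FPKM) and ATF3 (31.6 FPKM), the median was -0.27, and with library weights it was -0.21.

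Of 19 measured epithelial genes 13 were lower (median log2 fold change -0.40, camera adjusted p = 0.0015; adjusted p = 0.602 with an estimated correlation), and 4 passed adjusted over the list alone. These were EPCAM, an adhesion molecule (26.1 ± 6.06 FPKM in PBS, 15.3 ± 0.59 in treated tumours), KRT7 (59.1 ± 31.1 and 19.1 ± 6.65), the tight junction gene CLDN1 (5.23 ± 1.44 and 2.03 ± 0.91) and JUP, which encodes plakoglobin (17.3 ± 3.34 and 11.4 ± 1.12). The abundant keratins KRT8, KRT18 and KRT19 did not share this direction, with log2 fold changes of 0.11, 0.13 and 0.26. The median was -0.16 with library weights, and -0.61 after rescaling to TPM, which lowered the median of all genes to -0.23.

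Hypoxia response genes were lower for 22 of 26 members (median log2 fold change -0.28, camera adjusted p = 0.0034; adjusted p = 0.602 with an estimated correlation), and 0 passed adjusted over the list alone. VEGFA was at 60.4 ± 10.9 FPKM in PBS and 43.3 ± 11.9 in treated tumours, ADM at 49.2 ± 12.2 and 31.7 ± 6.93, and BNIP3L at 28.2 ± 4.16 and 21.2 ± 2.44. CA9, a carbonic anhydrase widely used as a hypoxia marker, went the other way, at 6.38 ± 2.54 and 14.6 ± 4.33 FPKM. The call ended without PBS replicate 1 (adjusted p = 0.0997) and without treated replicate 1 (adjusted p = 0.156), while the median stayed at -0.26 and -0.31. Another split of the libraries gave a larger absolute median (0.43).

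DNA replication genes were lower for 22 of 29 members, with a median log2 fold change of -0.13 (camera adjusted p = 0.047; adjusted p = 0.602 with an estimated correlation). RRM2 was at 32.3 ± 4.63 FPKM in PBS and 24.6 ± 3.44 in treated tumours, and UHRF1 at 19.6 ± 1.23 and 15.7 ± 2.00. This call ended in 12 of 24 alternative settings, among them median-of-ratios scaling (adjusted p = 0.0636, median -0.05) and leaving out PBS replicate 2 or 3 or treated replicate 1 or 2 (adjusted p = 0.0531, 0.0653, 0.165 and 0.0632, with medians of -0.14, -0.14, -0.16 and -0.10). Another split of the libraries gave a larger absolute median (0.14). Mitotic cell cycle genes did not pass (18 of 30 lower, median -0.05, adjusted p = 0.648).

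Cytosolic ribosomal protein genes were higher for all 47 members, 28 of them with no overlap between groups (median log2 fold change 0.43, camera adjusted p = 1.6e-16; adjusted p = 0.602 with an estimated correlation, which was itself 0.878). RPL9 was at 537 ± 55.1 FPKM in PBS and 759 ± 53.0 in treated tumours, and RPS9 at 691 ± 55.3 and 1058 ± 253. Without treated replicate 2 the median was 0.17 (adjusted p = 1.1e-09). With quantile normalization it was 0.08 and the call ended (adjusted p = 0.0555), and with library weights it was 0.19. Rescaling to TPM gave 0.23, which relative to the median of all genes was 0.46, against 0.47 before. TPM divides each library by 1 factor, so the relative value could hardly change.

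Oxidative phosphorylation genes were higher for 35 of 38 members (median log2 fold change 0.36, camera adjusted p = 8.1e-10; adjusted p = 0.602 with an estimated correlation). UQCRQ, of complex III, was at 39.6 ± 4.81 FPKM in PBS and 68.5 ± 26.7 in treated tumours, and NDUFA2, of complex I, at 72.3 ± 5.28 and 122 ± 46.7. Without treated replicate 2 the median was 0.13, with library weights 0.14 and with quantile normalization 0.19. Rescaling to TPM gave 0.16, which relative to the median of all genes was 0.39, against 0.40 before, and here too could hardly change. Both lists hold short transcripts, with median lengths of 693 and 702.5 nt against 1700 nt for all tested genes. Values fell with transcript length most in treated replicate 2 and less in treated replicate 3 (rank correlations -0.24 and -0.09). They rose with length in treated replicate 1 and in the PBS libraries. With a trend with length removed from every library the medians were still 0.38 for ribosomal proteins and 0.31 for oxidative phosphorylation (adjusted p = 4.3e-14 and 3.4e-08).

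The other 22 lists tested did not pass in the comparison as planned. Adjusted p-values of camera closest to the threshold were 0.0717 for fatty acid oxidation (median log2 fold change 0.14), 0.0747 for lysosome and autophagy (0.08), 0.0747 for fibroblast and matrix markers (0.18) and 0.0899 for angiogenic factors (-0.29). PI3K-AKT-FOXO targets had median log2 fold change -0.16 (adjusted p = 0.128), heat shock genes -0.14 (0.217) and fatty acid synthesis and storage -0.10 (0.306). Apoptosis regulators had -0.11 (0.396), genes of the unfolded protein and integrated stress response 0.04 (0.433) and mesenchymal genes -0.18 (0.472). Type I interferon response (-0.19), histones (0.00) and invasion and protease genes (0.10) each had adjusted p = 0.538. Glycolysis (0.05) and prostate luminal genes (-0.10) each had 0.672, squamous and basal keratins (-0.21) had 0.744, and cholesterol synthesis (-0.04), oxidative stress response (-0.05), endothelium and pericyte markers (-0.07) and adipocyte markers (-0.04) each had 0.903. For the list of invasion and protease genes the median was positive while the mean was -0.02, for glycolysis the mean was -0.03. Neuroendocrine genes had too few measured members (4) for a test, and mitochondrially encoded genes were not analysed here.

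Several of these lists passed camera in some alternative settings. Fibroblast and matrix markers passed as higher with library weights (median 0.40, adjusted p = 1.1e-04) and with the length trend removed (0.015). They also passed without PBS replicate 2 (0.0307), treated replicate 2 (0.0235) or treated replicate 3 (0.024), but their median was 0.00 without treated replicate 1. After TPM they passed (0.0324) with a median of only 0.007, against a median of -0.23 for all genes. Heat shock genes passed as lower with quantile normalization (median -0.41, adjusted p = 0.0013), without PBS replicate 2 (-0.22, 0.006) and without treated replicate 2 (-0.30, 0.0026), and their median was -0.02 without PBS replicate 1. Angiogenic factors passed as lower with a mean FPKM of at least 5 (adjusted p = 0.0148), with median-of-ratios (0.0452) and quantile normalization (0.0331) and without PBS replicate 2 (0.0451) or 3 (0.0166). Fatty acid oxidation passed as higher with no filter (adjusted p = 0.0326), with median-of-ratios scaling (0.04455), with library weights (0.0158) and without PBS replicate 2 (0.033), PBS replicate 3 (0.0104) or treated replicate 3 (0.024). Its median was 0.01 without PBS replicate 1 and 0.07 without treated replicate 2, against 0.14 as planned. Lysosome and autophagy genes passed as higher with no filter (adjusted p = 0.0141), with median-of-ratios scaling (0.0452), with library weights (0.04445) and without treated replicate 3 (0.024). The lysosome and autophagy median was 0.04 without PBS replicate 1 and 0.03 with the length trend removed, against 0.08 as planned. PI3K-AKT-FOXO targets passed as lower with a mean FPKM of at least 5 (median -0.25, adjusted p = 0.0055) and with an FPKM of at least 1 in 3 libraries (0.0448). Genes of the unfolded protein and integrated stress response passed as higher with library weights (adjusted p = 0.0387) and without treated replicate 3 (0.0061). Invasion and protease genes passed as higher with library weights (0.0245), and mitotic genes as lower without treated replicate 2 (0.038). The stress response median turned to -0.07 without treated replicate 2. Without PBS replicate 3 the medians turned to -0.01 for invasion and protease genes and 0.01 for mitotic genes. Mesenchymal genes passed as lower with quantile normalization (median -0.19, adjusted p = 0.02485), but their median was 0.05 with a mean FPKM of at least 5, 0.02 with library weights and -0.05 without PBS replicate 1 or treated replicate 2. The interferon and histone lists passed in either direction, depending on the library left out.

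Markers of mouse host cells were compared because reads from mouse stroma can map to conserved human sequence. The difference between treated and PBS tumours in mean log2(FPKM + 1) was 0.02 for fibroblast and matrix markers, -0.06 for endothelium and pericyte, -0.004 for macrophage and myeloid, 0.03 for lymphocyte, -0.06 for skeletal muscle, -0.05 for adipocyte, -0.06 for skin and -0.02 for erythroid markers. The exact two-sided permutation p-values were 0.5 to 0.9, where 0.1 is the smallest that 3 against 3 libraries can give. These means ran over all listed members, and members near 0 pull a difference toward 0. A mean FPKM of at least 1 was reached by 12 of 21 fibroblast, 8 of 20 endothelium and 3 of 22 macrophage markers. Over the 12 fibroblast and matrix markers alone the median log2 fold change was 0.18. Most macrophage markers were near 0: FCER1G was at 0.54 ± 0.23 FPKM in PBS and TYROBP at 0.07 ± 0.06. CD68 (34.2 ± 5.22 FPKM) and S100A9 (65.7 ± 13.6 FPKM) were higher, and both genes are also expressed outside the myeloid lineage.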

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

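Ignoring the status was a planned setting, but its use here and the other checks in this part were chosen after the results they bear on were seen.

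PTPN5, which encodes a tyrosine phosphatase (chromosome 11, 18749475 to 18814268), was left out of the comparison because its value in 1 PBS library had a failed quantification status. Its treated values, all with status OK, were 31.4 to 70.4 FPKM (mean 48.7, SD 19.9), above the PBS values of 13.9 to 29.02 FPKM (mean 21.9, SD 7.63). The highest PBS value is the one with the failed status. With the status ignored PTPN5 was among the genes tested, of which 0 passed (limma, smallest adjusted p = 0.132, 1057 genes at an unadjusted p under 0.05). PTPN5 was picked by a rule that looked only for higher treated values among the 24 rows set aside. SLC25A36 separated the other way, at 8.71 to 10.54 FPKM in PBS and 5.87 to 8.09 in treated tumours. So did PCBP2-OT1, at 0.58 to 0.78 and 0.25 to 0.49 FPKM. By chance 10% of rows would separate on average.

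MSMP, a small secreted protein of the microseminoprotein family (chromosome 9, 35752988 to 35754274), was also set aside for its status. It had 20392 to 28704 FPKM in the 3 PBS libraries and 28420 in treated replicate 3, but was listed at 0 in treated replicates 1 and 2. RGP1, which overlaps it, was listed at 0 in the same libraries and at 5.18 to 6.58 FPKM in the others. In the 2 libraries with a value of 0 the status says that the locus held too many fragments to be quantified, and in the other 4 it was OK. The zeros and that status thus coincided in 2 libraries, and the level of MSMP and RGP1 there was not measured.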

How the results depend on the processing

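No gene passed in the main comparison. The count was 1 with a pseudocount of 0.1, 0.01, no filter or robust moderation, 2 with an FPKM of at least 1 in 3 libraries, 3 with library weights and 0 to 6 without 1 library (6 without treated replicate 2, 4 without PBS replicate 3). Nearly all of these were small RNA genes; the exception was KLK4, with library weights and without treated replicate 2. The replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.144, -0.091 and 0.132), and with the replicate block 0 genes and 7 lists passed, with DNA replication lost (adjusted p = 0.0556) and angiogenic factors gained (0.0457). The 24 genes named by the rule kept their sign in every setting that gave a value.

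The number of lists passing was 12 with library weights, 5 to 12 without 1 library (11 without treated replicate 2, 12 without treated replicate 3), 0 with an estimated correlation and 0 with fry. Over the other 24 settings the cytokine (-0.84 to -0.42), immediate-early (-0.64 to -0.21), epithelial (-0.61 to -0.16) and oxidative phosphorylation (0.13 to 0.49) lists passed each time. Ribosomal proteins (0.08 to 0.55) passed in all but 1, hypoxia (-0.49 to -0.21) in all but 2, and DNA replication (-0.33 to -0.05) in 12. All 24 kept camera with the preset correlation, so they do not bear on that choice. TPM moved the median of all genes from -0.04 to -0.23. Relative to it the cytokine list stood at -0.60, ribosomal proteins at 0.46 and oxidative phosphorylation at 0.39. TPM divides each library by 1 factor, so these relative values could hardly change. Glycolysis reversed with quantile normalization (-0.252, adjusted p = 0.003). Without 1 library the interferon list ranged from -0.627 to 0.215 and histones from -0.157 to 0.189. The sign of both turned without treated replicate 2 and without PBS replicate 2. Interferon passed as lower without PBS replicate 1 (adjusted p = 6.5e-05) and as higher without treated replicate 2 (0.00985), and histones as lower without treated replicate 2 (0.012) and as higher without treated replicate 3 (0.0399). The causes were not tested.

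Host marker differences moved by more than their spread with other pseudocounts and with TPM, toward lower values in treated tumours. With a pseudocount of 0.01 they were -0.153 (fibroblast), -0.336 (endothelium), -0.110 (macrophage), -0.125 (lymphocyte), -0.630 (muscle), -0.335 (skin) and -0.304 (erythroid), and with 0.1 -0.181 (endothelium), -0.207 (muscle), -0.180 (skin) and -0.127 (erythroid). After TPM they were -0.176 (endothelium), -0.068 (macrophage), -0.140 (muscle), -0.149 (skin) and -0.055 (erythroid). Without counts, the depth behind low values is unknown.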

Other observations

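Leaving out a library and quantile normalization were planned settings, but their use as tests of the patterns in this part was chosen after the results were seen, as were the tests of length, GC content and host macrophages; the other splits of the libraries were planned.

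The heat shock genes HSPA1A, HSPA1B and DNAJB1 were lower in every treated tumour than in any PBS tumour, although the heat shock list passed only with quantile normalization (median -0.41), without PBS replicate 2 (-0.22) and without treated replicate 2 (-0.30), and was at -0.02 without PBS replicate 1. HSPA1A was at 130 ± 45.7 FPKM in PBS and 66.4 ± 6.17 in treated tumours (SD, n = 3 each), HSPA1B at 115 ± 37.5 and 57.7 ± 3.85, and DNAJB1 at 128 ± 40.9 and 82.7 ± 4.61, with the highest values in PBS replicate 1. HSPA1A and HSPA1B are near-identical copies and share reads. In other lists, PDGFB, a growth factor for pericytes, was at 11.5 ± 4.59 and 4.83 ± 2.07 FPKM, CDH2 (N-cadherin) at 6.72 ± 1.86 and 3.70 ± 0.40, TGFB2 at 1.67 ± 0.40 and 0.75 ± 0.11, and BAD, a promoter of apoptosis, at 87.5 ± 12.7 and 142 ± 32.2. None of these passed over all genes.

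Interferon-stimulated genes varied more between tumours of a group than between groups. The list's median deviation from the PBS mean was -0.878, 0.675 and 0.175 in PBS replicates 1, 2 and 3 and 0.219, -1.132 and 0.219 in the treated replicates. MIR210, singled out after its values were seen, was listed at 27.7, 12.5 and 6.32 FPKM in PBS and at 0 in all treated libraries, while MIR210HG, the host transcript, was at 14.0 ± 0.27 and 13.7 ± 9.28 FPKM. The libraries were made from polyadenylated RNA, so the MIR210 values were not read as levels of the mature microRNA.

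Single libraries did not carry the lower cytokine list, since the median log2 fold change was -0.51 without treated replicate 2 and -0.55 without PBS replicate 1, against -0.61 with all. Removing a length or GC trend left -0.57 and -0.51. Markers of host macrophages had a median of 0.12 FPKM in PBS, where the cytokine list was lower by a median of 2.75 FPKM. These are different genes, and how many mouse reads of each map to the human build is unknown. The comparison therefore cannot decide whether fewer reads from host macrophages play a part. The number of macrophages was not measured, and whether mouse reads were removed upstream is not given in the sources used here. In 1 of the 10 splits of the 6 libraries, the real one, the median was as large (0.61, highest other 0.48). The list was compared over the splits because it passed in the real one, which favours a large median there. Besides, 10 splits are too few for a share under 0.05. A response of the tumour cells to the peptide stays open as a hypothesis, as do tumour size, handling at resection and a receptor other than GHSR, none of which was tested.

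The higher ribosomal protein list depended more on the processing. Its direction held without treated replicate 2, but the median dropped from 0.43 to 0.17, so that library may supply most of its size. With quantile normalization the median was 0.0775 (quartiles of the members -0.01 and 0.20, before 0.32 and 0.50) and the call ended because the fold shrank. That method gives every library the same highest values. These genes have high values, so it can shrink a shift they share whatever its cause. Relative to the median of all genes the list stood at 0.47 before, 0.46 with TPM and 0.48 with median-of-ratios or upper-quartile scaling. Each of these scalings divides a library by 1 factor, so the relative value could hardly change and does not bear on normalization. With quantile normalization the relative value was 0.08. Normalization between libraries stays a candidate explanation that quantile normalization cannot decide, whereas the length trend alone left 0.38. In 1 of the 10 splits, the real one, the median was as large (0.43, highest other 0.34), again too few for a share under 0.05. This list too was compared because it passed in the real split, and it also passed in all 9 other splits. An effect of treatment stays open.

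Over the 10 splits, the number of genes past the threshold was at least the real 0 in 10 of them, as it must be against a count of 0 (highest other 4), the number at an unadjusted p under 0.05 was at least the real 1053 in 2 (highest other 1172; without PBS replicate 1 or 3 the real count was 531 or 333, and without treated replicate 2 or 3 it was 660 or 1709), and the number of lists was at least the real 7 in 8 (highest other 11). With 10 splits no share under 0.05 can be reached.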
